A study of Mus musculus with 32 samples.

How the data were processed

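Liver RNA of 32 Ldlr-/- mice was sequenced as total RNA with paired reads, per the labels. The deposited count tables, a table per sex, hold raw read counts per gene with a column per animal. They list 28329 genes for males and 28449 for females, each with at least 2 reads over the 16 libraries of its table. Per the submitters' processing notes, HTSeq (version not given), DESeq2 1.42.1 and the genome build GRCm38 were used. The aligner and the strand setting are not given in the sources used here. The deposited comparison tables hold, per the file headers, the authors' log2 fold changes and adjusted p-values of each diet against chow within a sex. The deposited KEGG tables hold, per the file headers, a normalized enrichment score for each pathway.

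Counts were used as deposited, for all 32 columns. Gene symbols came from the count tables, and coordinates (1-based, GRCm38) from GENCODE release M21, which held 29986 of the 30096 gene IDs (99.6%). Library totals ran from 20.9 M to 33.2 M reads. Library sizes were scaled with the trimmed mean of M-values (TMM), and levels are CPM on that scale, as mean ± SD over 4 animals. The 48 pairs of libraries within groups differed by a chi-square per gene of 20.2 to 112 over genes with at least 20 reads, so no library was a copy of another of its group.

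Each diet was compared with SD, and the diets with each other, within a sex, in a fit of the 16 libraries of that sex (12 residual degrees of freedom). The edgeR 4.0.16 quasi-likelihood F-test, which is two-sided, was run in R 4.3.3 with its default settings, after filterByExpr (minimum count 10, minimum total count 15), on 15996 genes in males and 16163 in females. The biological coefficient of variation was 0.161 in males and 0.188 in females. A fit of all 32 libraries (16786 genes, with a gene missing from a table entered as 0) gave the difference between the sexes on SD and the difference in response, as the female minus the male log2 fold change. Values of p were adjusted by Benjamini-Hochberg over the genes of a comparison, with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic.

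Before the data were examined, 37 gene lists, the comparisons, the main alternatives and the rule for naming genes were fixed. Lists with at least 5 measured genes were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The genes of a list past the threshold were also counted after adjustment over the list alone. For a diet against SD the named genes are the 8 with the largest and the 8 with the smallest log2 fold change among those past the threshold with a mean of at least 5 CPM and all 4 diet libraries above, or all 4 below, the 4 SD libraries. Gene models without a proper name were passed over. For the other comparisons the rule takes 5 in each direction, without the condition on overlap for the difference in response. It adds up to 4 genes of each list with the largest change past the threshold and a panel of 24 genes of lipid metabolism, fibrosis and inflammation. From these the text prefers genes whose call held under the alternatives. Genes with near-identical paralogs (among them Mup, Cyp2b, Cyp2c, Cyp3a, Cyp4a12, Serpina1 and Sult2a) can share reads, so values of a single member depend on how reads were assigned. The list is not complete, and other named genes may have the same limit.

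The alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, a filter of 1 CPM in 4 libraries, a robust spread estimate, the replicate number as a block, the animal number as a covariate, the 8 compared libraries alone, all 32 libraries in a single fit, an estimated correlation and each library left out in turn. Further settings were chosen after seeing the data. These leave out 3 female libraries with transcripts of other tissues, draw every library down to the lowest total, or add the clock score (log2 CPM of Dbp minus that of Bmal1, on edgeR's log scale) as a covariate. Replicate numbers were checked for pairing. Libraries with the same number in different groups had a mean correlation of residuals of 0.0023 in males and 0.029 in females. For other numbers the means were −0.0007 and −0.0092. Values for the same number ran from −0.17 to 0.19 in males and from −0.19 to 0.23 in females. In males 3 of 16 libraries and in females 7 of 16 went best with their own number. These values show no clear pairing but do not exclude a weak one, and the block is an alternative only.

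The procedure was tested on simulated counts with 200 changed genes. For WD against SD in males it recovered 43.3, 74.6 and 90.9% of genes changed 1.5-fold, 2-fold and 4-fold among 15005 genes, and for WD against SD in females 29.9, 62.7 and 89.4% among 15654 genes. For the difference in response to WD the shares were 17.9, 43.3 and 72.7%. In the real data 6781, 2345 and 1087 genes passed in these comparisons, and the adjusted p depends on how many genes change. The recovered shares therefore hold for the simulated setting and do not give the recovery in the real comparisons. The deposited KEGG tables and the authors' fold changes were read for comparison only.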

Results

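Liver RNA was sequenced from 32 Ldlr-/- mice, which lack the receptor that clears low-density lipoprotein from the blood. The animals formed 8 groups of 4, males and females on each of 4 diets for 24 weeks from 8 weeks of age. The diets were a standard chow (SD, 13% of calories from fat), a western diet (WD, 42% fat and 0.2% cholesterol), a diet without added choline (mCDHFD, 45% fat and 0.2% cholesterol) and a modified MASH diet with palmitic acid and trans-fat (mMASHD, 40% fat and 0.2% cholesterol). MASH is metabolic dysfunction-associated steatohepatitis, a fatty liver disease with inflammation. Each library held between 20.9 M and 33.2 M counted reads. The group means ± SD ran from 23.9 ± 2.16 M (male WD) to 31.96 ± 1.73 M (male mCDHFD). Mitochondrially encoded genes took 3.41 to 5.36% of the reads of a library. Reads of the targeted gene Ldlr were present in every group, at 543 ± 81.6 CPM (read counts scaled to library size, mean ± SD, n = 4) in males and 476.7 ± 103.4 CPM in females on SD. Counts per gene do not say which exons those reads cover, so they do not check the knockout. Xist, which silences the second X chromosome, stood at 478.4 ± 45.2 CPM in SD females and 2.04 ± 0.519 CPM in SD males, as the sex labels require.

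Clock genes differed between male SD and the male diet groups. Dbp (ENSMUSG00000059824) and Bmal1 (ENSMUSG00000055116) are circadian transcription factors whose transcripts peak at opposite times of day, and the clock score is log2 CPM of Dbp minus that of Bmal1 in the same library. Its mean was −2.07 ± 0.86 in male SD, 3.18 ± 0.71 in male WD, 2.39 ± 1.37 in male mCDHFD and 2.00 ± 2.20 in male mMASHD, where replicate 4 (−0.96) lay within the range of the SD animals. In females it was −3.48 ± 0.59 on SD, −1.11 ± 2.35 on WD, 0.67 ± 3.45 on mCDHFD and −1.56 ± 2.30 on mMASHD. The widest range within a group was 6.81 (female mCDHFD). Every comparison of a diet with SD was therefore also run with this score as a covariate, a setting chosen after seeing the data.

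**Figure D1:**
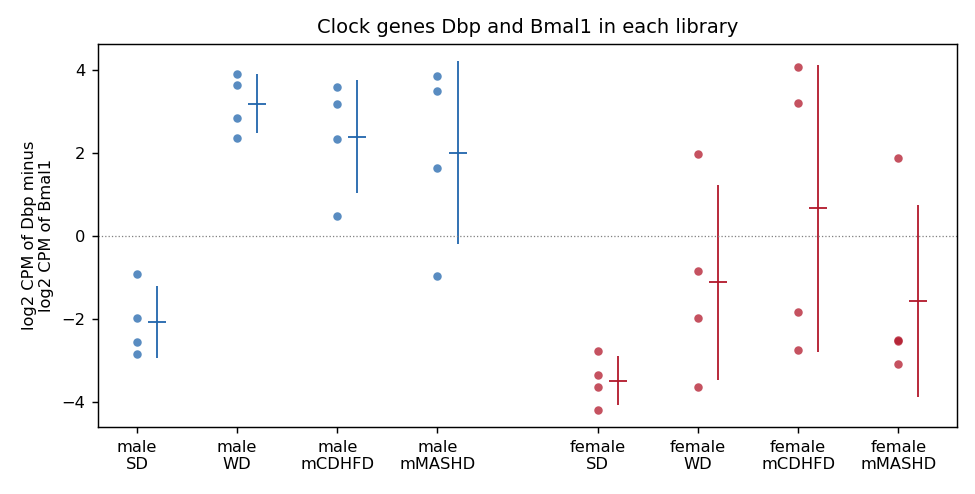
Clock score of each library (log2 CPM of Dbp minus log2 CPM of Bmal1, vertical axis) in the 8 groups, with the mean ± SD of 4 animals. Male SD has a mean of −2.07 and the male diets have means of 2.00 to 3.18.

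Some female libraries also stood high in genes of other tissues, and are called libraries with transcripts of other tissues here. In female WD replicate 4, all 16 genes of a skeletal muscle list were at their highest among the 16 female libraries, and Myh2, a muscle myosin, reached 115 CPM against at most 1.09 CPM elsewhere. All 6 genes of a fat list were also highest there. In female mMASHD replicate 3, 5 of 11 adrenal cortex genes were at their highest. In female SD replicate 4, 8 of 12 lymphoid genes were at their highest. The fat genes there had a median of 16.7 times their median elsewhere, but at a low level (a median of 1.13 against 0.0742 CPM). Comparisons with females were also run without these 3 libraries, a setting chosen after seeing the data. In the comparisons given next, within a sex or between the sexes on SD, all 4 libraries of a group lay on the same side of all 4 of the other for each gene given with a fold change from the main fit, except Pemt on mCDHFD and Cyp51 and Sqle on mMASHD in males, and Marco, Adgre1 and Tnf between the sexes.

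In males, WD was compared with SD to find which liver genes respond to a high-fat, high-cholesterol diet. Genes of lipid-laden macrophages were among those that rose. Gpnmb, a glycoprotein of such macrophages (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929), rose from 4.74 ± 0.8497 CPM on SD to 214 ± 76.1 CPM on WD, a log2 fold change of 5.49 ± 0.28 (SE, adjusted p = 1.04e-09). Mmp12, a macrophage elastase (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499), rose by 5.28 ± 0.20 (adjusted p = 6.3e-11), and Trem2, a lipid receptor of macrophages (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147), by 4.03 ± 0.28. The chemokines Ccl2 and Cxcl1, which attract monocytes and neutrophils, rose by 3.93 ± 0.34 and 3.89 ± 0.42. The calcium-binding neutrophil protein S100a8 rose by 3.64 ± 0.55. Col1a1, the main fibrillar collagen of scar tissue (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), rose from 12.4 ± 6.54 to 128.1 ± 28.4 CPM, a log2 fold change of 3.37 ± 0.34 (adjusted p = 6.54e-07), and Timp1, an inhibitor of matrix breakdown, by 4.07 ± 0.37. Cidea, a protein of lipid droplets (ENSMUSG00000024526, chromosome 18, 67343604 to 67367785), rose from 2.21 ± 0.261 to 55.8 ± 37.3 CPM. As groups, 24 of 24 genes of the collagen and matrix list rose (24 adjusted over the list alone, median log2 fold change 1.49), as did 22 of 22 genes of the monocyte and chemokine list (22 adjusted over the list alone, median 2.89) and 18 of 20 interferon response genes (19 adjusted over the list alone, median 1.66), among them the antiviral gene Oas1a (2.33 ± 0.18). Of the lipid-associated macrophage markers 14 of 16 rose and 1, the lipid droplet gene Plin2 (−0.71 ± 0.15), fell. Neutrophil markers rose in 10 of 11 genes and Kupffer cell markers in 11 of 12.

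Genes of cholesterol synthesis and fatty acid oxidation fell in the same livers, while some genes of lipid synthesis rose. Cyp51, a demethylase of cholesterol synthesis (ENSMUSG00000001467, chromosome 5, 4081145 to 4104746), fell from 51.3 ± 6.92 to 9.88 ± 1.00 CPM, a log2 fold change of −2.38 ± 0.20 (adjusted p = 8.9e-08). Sqle, the squalene epoxidase of that pathway (ENSMUSG00000022351, chromosome 15, 59315077 to 59331192), changed by −2.12 ± 0.31, Idi1 by −3.52 ± 0.46 and Pcsk9, which degrades the LDL receptor, by −1.91 ± 0.27. The cholesterol synthesis list fell in 19 of 23 genes (19 adjusted over the list alone, median −0.71). Cyp4a14, a fatty acid hydroxylase (ENSMUSG00000028715, chromosome 4, 115486200 to 115496142), fell from 6051 ± 1233 to 1015 ± 454.1 CPM, and 20 of 23 fatty acid oxidation genes fell (20 adjusted over the list alone, median −0.70). The desaturase Scd1 (ENSMUSG00000037071, chromosome 19, 44394455 to 44407879) rose by 2.51 ± 0.23 and Srebf1, a regulator of lipid synthesis, by 1.67 ± 0.23. The fatty acid synthesis list passed as a set by camera (median 0.33). With the clock score as a covariate its median was 0.05 (camera adjusted p = 0.359), and with an estimated correlation its adjusted p was 0.423. Male-biased liver genes fell in 16 of 20 (16 adjusted over the list alone, median −2.25). Of the urinary pheromone carriers, Mup7 (ENSMUSG00000073842, chromosome 4, 60066469 to 60070475) changed by −5.52 ± 0.60 and Mup1 by −4.08 ± 0.38, and reads can be shared between these near-identical paralogs. Moxd1, a monooxygenase (ENSMUSG00000020000, chromosome 10, 24223517 to 24302790), fell from 38.4 ± 30.3 to 0.311 ± 0.0683 CPM (log2 fold change −6.92 ± 0.78, and −6.34 without male SD replicate 3). The bile acid genes Cyp7b1 (−2.80 ± 0.29) and Cyp8b1 (−2.09 ± 0.21) were among 12 of 21 genes of their list that fell.

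In all, 6781 of 15996 tested genes passed an adjusted p of 0.05 in males on WD, 3511 higher and 3270 lower, and 2047 rose and 449 fell at least 2-fold. As sets, 12 lists rose and 9 fell, 2 and 1 of them also with an estimated correlation. The macrophage and monocyte lists (camera adjusted p = 2.64e-30 and 1.22e-24) and the male-biased list (1.48e-13) also passed with an estimated correlation (adjusted p = 0.022, 0.022 and 0.0456), whereas the collagen (1.13e-15) and cholesterol synthesis lists (4.77e-09) did not (adjusted p = 0.155 and 0.176 with an estimated correlation). The fatty acid oxidation list (2.68e-10) and the interferon list (4.22e-13) each had an adjusted p = 0.155 with an estimated correlation. With the clock score as a covariate 2291 genes passed, 2214 of them among the 6781. The clock genes Dbp (3.27 ± 0.56) and Per3 (2.33 ± 0.44) rose and Bmal1 (−1.85 ± 0.33) fell.

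In males, mCDHFD was compared with SD to find the response to a high-fat, high-cholesterol diet without added choline. Mmp12 (4.89 ± 0.20, adjusted p = 1.97e-10), Gpnmb (4.73 ± 0.28) and Trem2 (3.84 ± 0.27) were again far above SD. Lcn2, an iron-binding acute phase protein (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252), rose by 4.75 ± 0.52 and the neurotrophin receptor Ntrk2 by 4.81 ± 0.27. Col1a1 reached 171.7 ± 30.6 CPM against 12.4 ± 6.54 CPM (log2 fold change 3.796 ± 0.35, adjusted p = 2.78e-07), and Timp1 rose by 4.72 ± 0.36. All 24 collagen and matrix genes rose (24 adjusted over the list alone, median 1.70), 21 of 22 monocyte and chemokine genes rose (21 adjusted over the list alone, median 2.75), and Ccl2 rose by 4.08 ± 0.34. Acute phase genes rose in 11 of 20 (11 adjusted over the list alone), with Saa3 at 3.17 ± 0.33 and the ferrireductase Steap4 at 3.37 ± 0.23. Neutrophil markers rose in 11 of 11 genes, and cell cycle genes in 16 of 22, among them the proliferation marker Mki67 (2.81 ± 0.36) and Top2a (2.17 ± 0.22).

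Genes of fatty acid oxidation and hydroxylation were among those that fell. Cyp4a14 fell from 6051 ± 1233 to 360.1 ± 34.6 CPM (log2 fold change −4.07 ± 0.36, adjusted p = 2.3e-07), the thioesterases Acot3 and Acot1 changed by −3.57 ± 0.41 and −3.07 ± 0.28, and the peroxisomal enzyme Ehhadh by −2.36 ± 0.25. Fatty acid oxidation genes fell in 20 of 23 (21 adjusted over the list alone, median −0.70) and cholesterol synthesis genes in 18 of 23 (19 adjusted over the list alone, median −0.77), with Sqle at −2.28 ± 0.31, Cyp51 at −2.25 ± 0.20 and Tm7sf2 at −2.32 ± 0.20. The organic anion carrier Slco1a1 (−3.33 ± 0.36), the bile acid enzyme Cyp8b1 (−2.30 ± 0.21) and the uptake carrier Slc10a1 (−1.04 ± 0.12) fell. Drug-metabolising enzymes fell in 17 of 22 genes, among them the carboxylesterase Ces2a (−2.28 ± 0.17). Cyp2b9, a female-biased cytochrome P450 (ENSMUSG00000040660, chromosome 7, 26173411 to 26210661), rose from 2.498 ± 0.766 to 37.5 ± 22.3 CPM (log2 fold change 3.90 ± 0.52, adjusted p = 1.43e-05). Of the choline, methionine and phospholipid genes 13 of 22 fell and 1 rose, with Mthfr, the folate cycle reductase, at −1.57 ± 0.21. Pemt, which makes phosphatidylcholine from phosphatidylethanolamine, changed by −0.32, and by −0.23 (adjusted p = 0.0747) and −0.25 (adjusted p = 0.0656) without male mCDHFD replicates 3 and 4. It was at −0.23 with the clock score as a covariate (adjusted p = 0.346) and −0.31 with the 8 compared libraries alone (adjusted p = 0.0584).

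In this comparison 6628 genes passed, 3499 higher and 3129 lower, and 12 lists rose and 10 fell, 2 and 0 of them also with an estimated correlation. The macrophage (camera adjusted p = 1.86e-27) and monocyte lists (4.93e-23) also passed with an estimated correlation (adjusted p = 0.0224 for each), but not the collagen, fatty acid oxidation and cholesterol synthesis lists (1.78e-20, 1.16e-12 and 2.22e-10, against adjusted p = 0.109, 0.109 and 0.138 with an estimated correlation). The acute phase, drug-metabolising and cell cycle lists (1.48e-06, 1.48e-06 and 2.55e-05) had adjusted p = 0.299, 0.178 and 0.208 with an estimated correlation. With the clock score as a covariate 2897 genes passed, 2782 of them among the 6628.

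In males on mMASHD, the question was the response to a diet with palmitic acid and trans-fat. Among genes with a mean of at least 5 CPM over the male libraries Cidea had the largest rise, from 2.21 ± 0.261 to 109.7 ± 25.9 CPM (log2 fold change 5.63 ± 0.43, adjusted p = 2.64e-07), followed among macrophage genes by Mmp12 (4.26 ± 0.20), Trem2 (3.03 ± 0.27) and Gpnmb (2.80 ± 0.26). The fatty acid carrier Cd36 (1.93 ± 0.20), the acyltransferase Mogat1 (2.21 ± 0.22), Fabp4 (2.07 ± 0.31) and Scd1 (2.53 ± 0.23) rose with it. Lipid droplet and uptake genes rose in 10 of 20 and fell in 2 (median 0.67), and fatty acid synthesis genes rose in 11 of 20 (median 0.57). Col1a1 rose by 3.27 ± 0.34 to 119.1 ± 44.5 CPM, Timp1 by 4.11 ± 0.37 and 24 of 24 collagen and matrix genes rose (24 adjusted over the list alone, median 1.51). Bile duct cell markers rose in 9 of 13 (9 adjusted over the list alone, median 1.59), among them the tetraspanin Tspan8 (ENSMUSG00000034127, chromosome 10, 115816832 to 115849893), at 2.98 ± 0.44, and Cd24a at 2.45 ± 0.38. Cholesterol synthesis genes went both ways, with 4 of 23 higher and 6 lower. With the clock score as a covariate 0 were higher and 5 lower, and the list median went from −0.14 to −0.28. Cyp51 changed by −0.74 ± 0.19 (adjusted p = 0.00525), while Sqle was at 12.6 ± 6.22 CPM against 13.2 ± 3.56 CPM on SD. Mup1 changed by −3.91 ± 0.37 and the selenium-binding protein Selenbp2 (ENSMUSG00000068877, chromosome 3, 94693556 to 94704413) by −2.47 ± 0.47, and male-biased genes fell in 12 of 20. Drug-metabolising enzymes fell in 15 of 22, with Cyp3a11 at −1.82 ± 0.27.

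On mMASHD 5658 genes passed in males, 3097 higher and 2561 lower, and 13 lists rose and 9 fell, 1 and 0 of them also with an estimated correlation. The macrophage list alone (camera adjusted p = 9.68e-28) also passed with an estimated correlation (adjusted p = 0.0309). The collagen (7.75e-22), monocyte (1.2e-18), lipid droplet (4.29e-05) and bile duct lists (0.00297) had adjusted p = 0.123, 0.0681, 0.123 and 0.47 with an estimated correlation, and the bile duct list had 0.0696 with the clock score as a covariate, where its median was 1.41. With that covariate 1803 genes passed, 1729 of them among the 5658.

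In females, WD raised the same macrophage genes. Gpnmb rose from 4.28 ± 1.102 to 163.3 ± 90.7 CPM (log2 fold change 5.25 ± 0.54, adjusted p = 7.34e-06), Mmp12 by 4.63 ± 0.39 and Trem2 by 4.30 ± 0.31 (1.44 ± 0.329 to 28.4 ± 11.4 CPM). The fungal pattern receptor Clec7a (3.14 ± 0.25), the Langerhans cell lectin Cd207 (3.21 ± 0.46) and the metalloprotease-like Adam11 (3.14 ± 0.30) rose with them. Saa3, an acute phase protein of macrophages, went from 7.99 ± 0.890 to 70.0 ± 28.6 CPM (3.13 ± 0.26, adjusted p = 1.94e-06), and the chemokines Cxcl2 and Ccl6 rose by 3.98 ± 0.35 and 2.25 ± 0.15. Col1a1 rose from 9.67 ± 4.22 to 59.8 ± 23.3 CPM (2.63 ± 0.38, adjusted p = 0.000188). The collagen and matrix list rose in 19 of 24 genes (22 adjusted over the list alone, median 0.86), the macrophage list in 14 of 16 (14 adjusted over the list alone, median 2.14), the monocyte and chemokine list in 16 of 22 (18 adjusted over the list alone, median 1.55) and interferon genes in 13 of 20 (15 adjusted over the list alone, median 0.97). None of 9 neutrophil markers passed. Scd1 (2.85 ± 0.41), Scd2 (2.29 ± 0.18), Srebf1 (1.94 ± 0.22) and the lipoprotein lipase Lpl (2.75 ± 0.23) rose. Cyp51 fell from 37.6 ± 10.1 to 11.2 ± 2.72 CPM (−1.75 ± 0.19, adjusted p = 1.33e-05), and 7 of 23 cholesterol synthesis genes fell (11 adjusted over the list alone). The hepatokine Fgf21 changed by −1.79 ± 0.37. The scavenger receptor Cd163 fell from 19.9 ± 9.32 to 3.43 ± 2.82 CPM (−2.54 ± 0.53, −3.29 without female WD replicate 4 and −3.48 without the 3 libraries with transcripts of other tissues). H19, a fetal liver RNA, rose by 5.08 ± 1.16 (adjusted p = 0.00761), but by 3.50 without female WD replicate 4 (adjusted p = 0.0319) or without those 3 libraries (adjusted p = 0.0659).

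In females on WD 2345 of 16163 genes passed, 1516 higher and 829 lower, and 1522 did without female WD replicate 2. As sets 8 lists rose and 2 fell, 2 and 0 of them also with an estimated correlation. The macrophage and monocyte lists (camera adjusted p = 2.72e-33 and 9.82e-25) also passed with an estimated correlation (adjusted p = 0.0156 and 0.0198), unlike the collagen, interferon and cholesterol synthesis lists (4.53e-16, 1.99e-15 and 3.8e-06, against adjusted p = 0.161, 0.161 and 0.417 with an estimated correlation). For the neutrophil markers camera gave an adjusted p of 0.781.

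Females on mCDHFD were compared with SD in the same way. Mmp12 (5.31 ± 0.40, adjusted p = 1.27e-06), Gpnmb (4.99 ± 0.53) and Trem2 (4.53 ± 0.31) rose, as did the oestrogen sulfotransferase Sult1e1 (4.47 ± 0.73) and the fibrinolysis inhibitor Serpine1 (3.42 ± 0.42). Col1a1 reached 94.7 ± 42.0 CPM (3.29 ± 0.38, adjusted p = 2.16e-05), Timp1 rose by 4.24 ± 0.39, and 23 of 24 collagen and matrix genes rose (23 adjusted over the list alone, median 1.417). The macrophage list rose in 13 of 16 genes (15 adjusted over the list alone, median 2.20), the monocyte list in 16 of 22 (19 adjusted over the list alone, median 1.421), the interferon list in 17 of 20 (18 adjusted over the list alone, median 1.25) and the NRF2 and glutathione list in 11 of 19 (11 adjusted over the list alone, median 0.63). Sqle fell from 11.8 ± 5.69 to 2.48 ± 0.625 CPM (−2.25 ± 0.30, adjusted p = 8.06e-05), Cyp51 changed by −2.30 ± 0.19 and Idi1 by −3.14 ± 0.46, and cholesterol synthesis genes fell in 13 of 23 (15 adjusted over the list alone, median −0.59). Cd163 fell to 1.67 ± 1.095 CPM (−3.58 ± 0.56). Female-biased liver genes fell in 13 of 25 and rose in 3, with the transcription factor Cux2 at −2.71 ± 0.38. The phenobarbital-induced Cyp2b10 changed by −4.55 ± 0.88, and reads can be shared with other Cyp2b genes. The insulin signalling adaptor Irs2 changed by −1.94 ± 0.23 and Cyp4a14 by −1.36 ± 0.26.

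On mCDHFD 3230 genes passed in females, 1992 higher and 1238 lower, and 2120 did without female mCDHFD replicate 3. In all 11 lists rose and 6 fell, 1 and 0 of them also with an estimated correlation. With an estimated correlation the macrophage list alone passed (camera adjusted p = 1.69e-32, and adjusted p = 0.0163 with an estimated correlation), and the collagen, monocyte and interferon lists (1.79e-24, 4.57e-19 and 7.55e-18) had adjusted p = 0.0965, 0.0528 and 0.172. The cholesterol synthesis, NRF2 and female-biased lists (1.05e-09, 0.000176 and 0.000942) had adjusted p = 0.216, 0.317 and 0.291 with an estimated correlation. With the clock score as a covariate 1510 genes passed, 1413 of them among the 3230, against 1603 for females on WD and 1785 for females on mMASHD.

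On mMASHD the female livers showed the macrophage and matrix genes once more. Mmp12 (5.38 ± 0.40, adjusted p = 1.61e-06), Gpnmb (4.86 ± 0.53, to 124.4 ± 74.2 CPM) and Trem2 (4.42 ± 0.31) rose, together with Adam11 (3.30 ± 0.31), Clec7a (3.00 ± 0.25) and Cxcl2 (3.63 ± 0.35). Col1a1 rose by 2.80 ± 0.38 to 67.3 ± 23.7 CPM, and 22 of 24 collagen and matrix genes rose (23 adjusted over the list alone, median 1.03). The macrophage list rose in 14 of 16 genes (15 adjusted over the list alone, median 1.98) and the monocyte list in 15 of 22 (20 adjusted over the list alone, median 1.54). The immediate early gene Egr2 rose by 2.98 ± 0.40. Scd1 rose by 2.87 ± 0.41 and Mogat1 by 2.18. Cyp51 changed by −1.88 ± 0.19 (adjusted p = 1.09e-05) and 9 of 23 cholesterol synthesis genes fell (10 adjusted over the list alone, median −0.50). Sult2a7, a sulfotransferase (ENSMUSG00000094156, chromosome 7, 14465051 to 14494230), fell from 18.7 ± 8.01 to 1.74 ± 0.4504 CPM (−3.42 ± 0.63, adjusted p = 0.00168), and reads can be shared among Sult2a paralogs. B and plasma cell markers fell in 3 of 12 genes as a set (camera adjusted p = 0.0269, and adjusted p = 0.662 with an estimated correlation), but with an adjusted p of 0.763 without female SD replicate 4, the library high in lymphoid genes, of 0.944 without the 3 libraries, and of 0.0501 and 0.0534 without female mMASHD replicates 1 and 3.

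On mMASHD 2311 genes passed in females, 1548 higher and 763 lower, and 1379 did without female mMASHD replicate 2. In this comparison 8 lists rose and 6 fell, 2 and 0 of them also with an estimated correlation. The macrophage and monocyte lists (camera adjusted p = 1.06e-37 and 7.03e-26) also passed with an estimated correlation (adjusted p = 0.01 and 0.0184), and the collagen and cholesterol synthesis lists (1.31e-20 and 1.63e-06) did not (adjusted p = 0.175 and 0.367 with an estimated correlation).

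**Figure D2:**
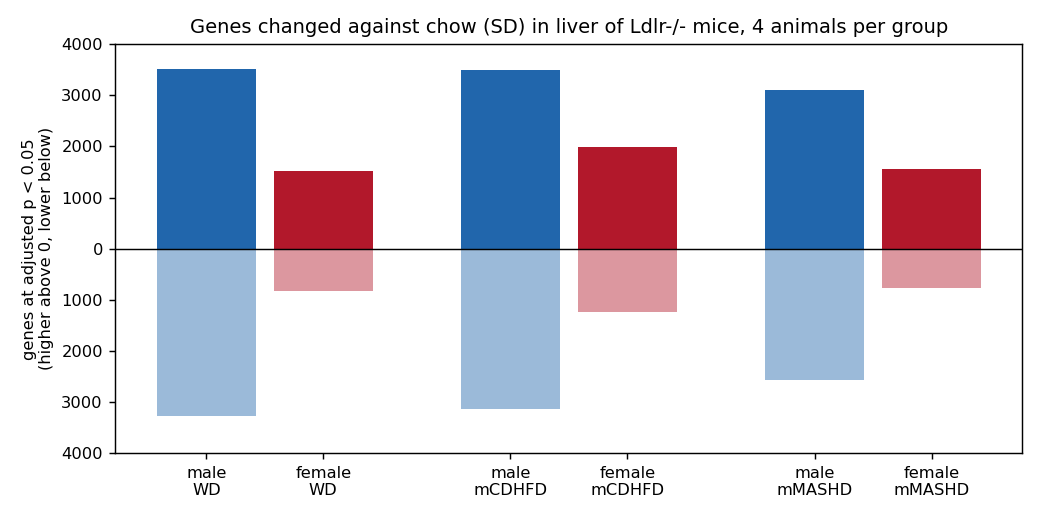
Number of genes past an adjusted p of 0.05 for each diet against SD, higher above 0 and lower below 0, in males (blue) and females (red). Males have 5658 to 6781 genes and females 2311 to 3230.

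**Figure D3:**
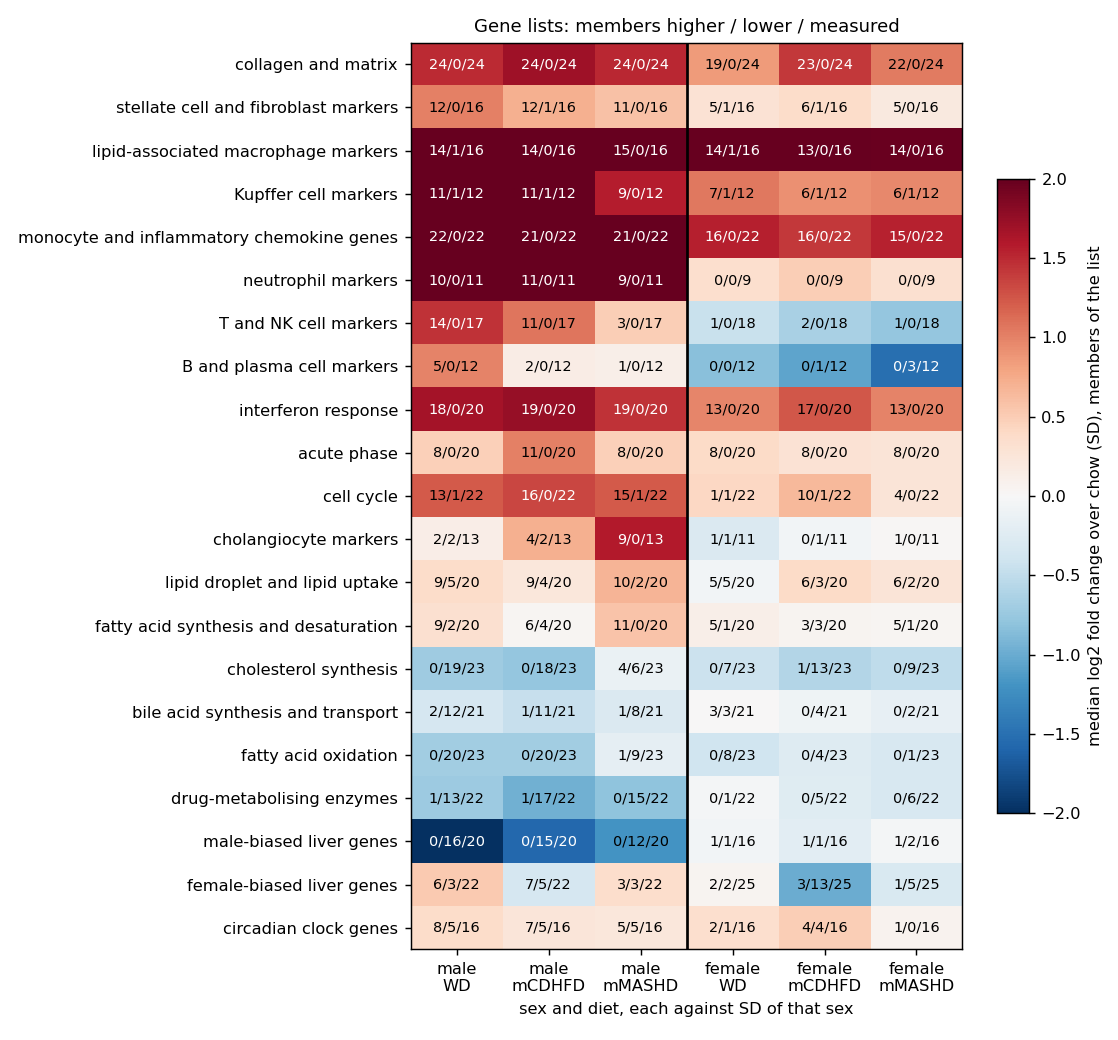
Median log2 fold change against SD of 21 gene lists (vertical axis) in the 6 comparisons of a diet with SD (horizontal axis), with colours saturating at ±2 and the genes higher, lower and measured in each cell. The collagen and matrix list has 24 of 24 genes higher on each male diet and 19 to 23 of 24 in females.

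**Figure D4:**
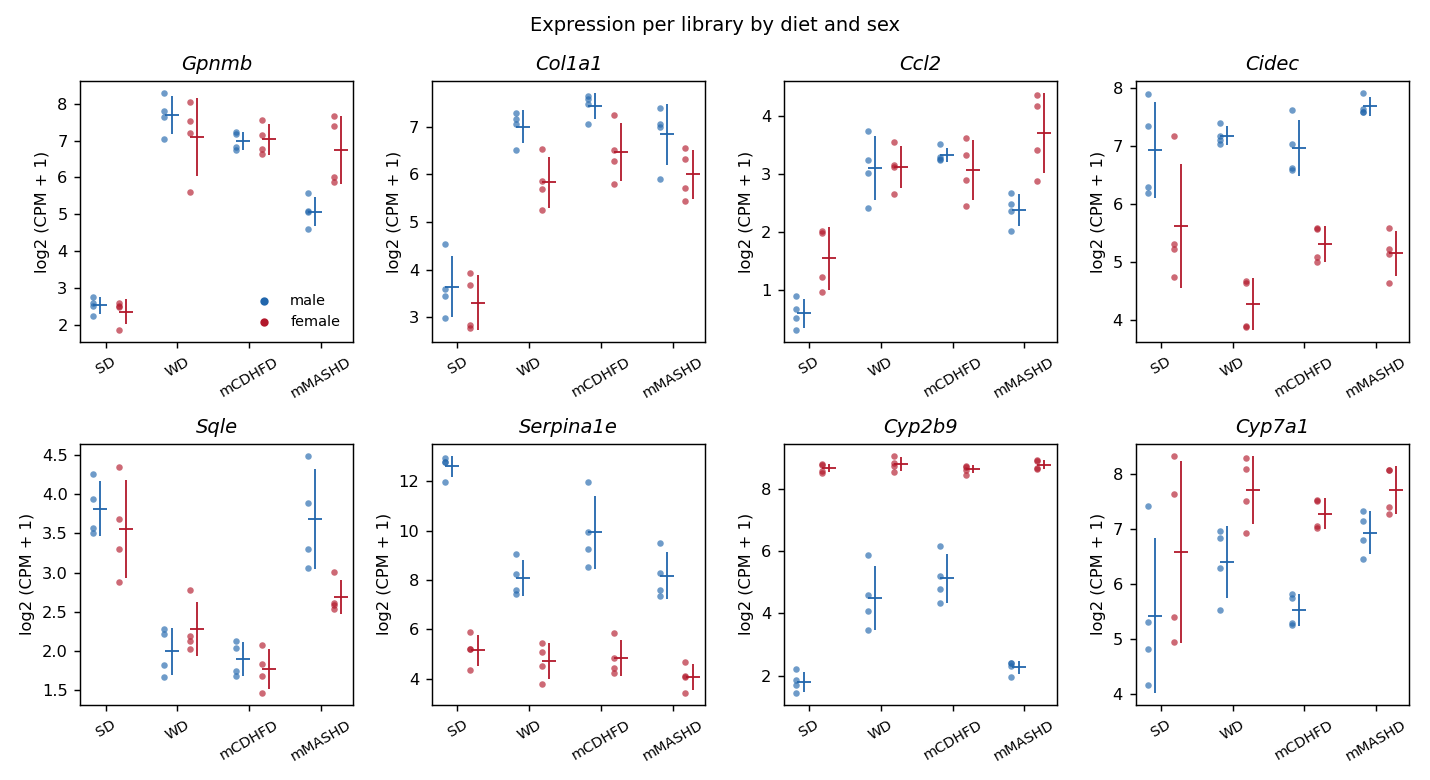
log2(CPM + 1) of 8 genes in each library, male in blue and female in red, with the mean ± SD of 4 animals for each diet. Gpnmb and Col1a1 lie above SD on every diet in both sexes, and Sqle lies near its SD level in males on mMASHD.

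Direct comparisons of the diets within males asked how they differ from each other. Between mCDHFD and WD 1 gene passed, Nipal1, a magnesium transporter, at 1.14 ± 0.407 CPM on mCDHFD and 4.72 ± 1.57 CPM on WD (adjusted p = 0.0318, chosen after its values were seen). By edgeR 1522 genes (9.5% of those tested) had an unadjusted p under 0.05, and DESeq2 called 64. The count was 0 without male WD replicate 1, 2 or 4 or male mCDHFD replicate 2, 3 or 4, and 2 without male mCDHFD replicate 1. By camera 8 lists were higher and 12 lower, 0 of them with an estimated correlation.

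Against WD, cholesterol synthesis genes were higher and several macrophage genes lower on mMASHD in males. Cyp51 was 1.64 ± 0.20 higher on the log2 scale (30.8 ± 11.5 against 9.88 ± 1.00 CPM, adjusted p = 0.000325), Sqle 2.05 ± 0.31, Idi1 3.01 ± 0.46 and Fdps 1.53 ± 0.18 higher. Of the list 15 of 23 genes were higher (20 adjusted over the list alone, median 0.69). Fatty acid oxidation genes were higher in 12 of 23 (20 adjusted over the list alone, median 0.43). Gpnmb was lower on mMASHD, at 33.1 ± 9.61 against 214 ± 76.1 CPM (−2.69 ± 0.24, adjusted p = 5.08e-05), as were the lysosomal proton pump subunit Atp6v0d2 (−1.65 ± 0.16), the galectin Lgals3 (−1.42 ± 0.16), Cd68 (−1.18 ± 0.15) and Cd5l (−1.29). The macrophage list was lower in 9 of 16 genes and higher in 1, the monocyte and chemokine list lower in 14 of 22 (17 adjusted over the list alone, median −0.96) and T and NK cell markers lower in 7 of 17. Bile duct cell markers were higher in 7 of 13 (9 adjusted over the list alone, median 1.16), with Tspan8 at 1.92 ± 0.40 and the adhesion molecule Epcam at 1.75 ± 0.35. The male-biased genes Mup7 (3.30 ± 0.54) and Susd4 (1.64 ± 0.16) were higher too, with 9 of 20 of their list. In all 1199 genes passed, 446 higher and 753 lower, but 516 without male WD replicate 2, 577 without male mMASHD replicate 2 and 732 without male mMASHD replicate 1. By camera the cholesterol synthesis, fatty acid oxidation, monocyte and bile duct lists had adjusted p = 1.41e-23, 1.15e-14, 7.04e-14 and 9.61e-09, and adjusted p = 0.0726, 0.0802, 0.0802 and 0.163 with an estimated correlation. The macrophage, T and NK and male-biased lists had 1.35e-12, 2.43e-09 and 1.17e-13, and adjusted p = 0.0802, 0.0802 and 0.0726 with an estimated correlation. In all 7 lists were higher and 8 lower, 0 of them with an estimated correlation.

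The other male pair, mCDHFD against mMASHD, also differed in lipid enzymes. Cyp2b9 (3.30 ± 0.49, adjusted p = 0.00164), Saa3 (2.07 ± 0.31) and Gpnmb (1.93 ± 0.24) were higher on mCDHFD. Cyp4a14 (−2.34 ± 0.34), Acot3 (−2.54 ± 0.40), Slco1a1 (−2.33 ± 0.35), Sqle (−2.21 ± 0.30), Tm7sf2 (−1.72 ± 0.19, adjusted p = 0.000424) and Cidea (−1.99 ± 0.34) were lower. Cholesterol synthesis genes were lower in 14 of 23 (19 adjusted over the list alone, median −0.81) and fatty acid oxidation genes in 11 of 23 (22 adjusted over the list alone, median −0.49). Both lists passed by camera (9.86e-32 and 5.85e-24) and with an estimated correlation (adjusted p = 0.0297 and 0.0464), unlike the other 19 of the 11 higher and 10 lower lists. In all 529 genes passed, 220 higher and 309 lower, but 214 without male mMASHD replicate 2, 218 without male mCDHFD replicate 3, 278 without male mMASHD replicate 1 and 319 without male mCDHFD replicate 2.

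In females few genes differed between the diets. On mCDHFD against WD 16 genes passed, 10 higher and 6 lower. They included the lysosomal gene Cln6 (1.02 ± 0.15, adjusted p = 0.0185), the antioxidant gene Srxn1 (0.89 ± 0.15) and Saa3 (−1.30 ± 0.23, adjusted p = 0.0442), and each named gene lost its call without at least 1 library. Srxn1 was at 0.84 (adjusted p = 0.0583) without the 3 libraries with transcripts of other tissues. The count was 0 without female WD replicate 1 or 3 or female mCDHFD replicate 1, 3 or 4, and 2 without female WD replicate 2. Female-biased liver genes were lower as a set (1 of 25 passed, 11 adjusted over the list alone, median −0.81, camera adjusted p = 7.24e-16), also with an estimated correlation (adjusted p = 0.0292), the only one of 9 higher and 9 lower lists to do so. By edgeR 1199 genes (7.4% of those tested) had an unadjusted p under 0.05, and DESeq2 called 133. Between mMASHD and WD 0 genes passed by edgeR, with 809 (5.0% of those tested, the share expected by chance) at an unadjusted p under 0.05 and 23 by DESeq2. Of these genes 2 passed without female WD replicate 4 or female mMASHD replicate 4. Between mCDHFD and mMASHD 0 passed by edgeR, with 967 (6.0%) at an unadjusted p under 0.05 and 77 by DESeq2, and 3 passed without female mCDHFD replicate 2.

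On SD, female and male livers differed in the known sex-biased genes. The sulfotransferase Sult2a1 was 8.56 ± 0.51 higher in females on the log2 scale (adjusted p = 2.78e-13), Sult3a1 8.61 ± 0.79, the steroid hydroxylase Cyp3a41a 8.44 ± 0.64 and Cyp2b9 7.31 ± 0.45 (409.9 ± 38.5 against 2.498 ± 0.766 CPM). Mup7 (−9.37 ± 0.64), the arachidonic acid hydroxylase Cyp4a12a (−7.74 ± 0.31, adjusted p = 1.38e-17) and the Y-linked Eif2s3y (−7.22 ± 0.19) were lower. All 25 genes of the female-biased list were higher (25 adjusted over the list alone, median 6.86, and 5.93 without female SD replicate 1) and all 20 of the male-biased list were lower (20 adjusted over the list alone, median −5.38). Immune genes were higher in SD females. Kupffer cell markers were higher in 11 of 12 genes (11 adjusted over the list alone, median 1.24), with Clec4f at 1.15 ± 0.20, monocyte and chemokine genes in 15 of 22 (18 adjusted over the list alone, median 1.303), with Ccl2 at 1.95 ± 0.48, and neutrophil markers in 6 of 11, with Cxcr2 (ENSMUSG00000026180) at 3.19 ± 0.60. Part of this came from female SD replicate 3, without which 9 Kupffer and 13 monocyte genes were higher (medians 0.86 and 0.88). Without it the macrophage receptor Marco went from 2.78 to 0.66 (adjusted p = 0.582), the macrophage marker Adgre1 from 1.86 to 0.95 (adjusted p = 0.0791), Timd4 from 2.11 to 1.46 (adjusted p = 0.0479) and the cytokine Tnf from 1.84 to 0.74 (adjusted p = 0.415). B and plasma cell markers were higher in 9 of 12 genes, but in 1 without female SD replicate 4, and the set had an adjusted p of 0.103 without female SD replicate 4 and of 0.0662 without the 3 libraries, against 0.002 with it (adjusted p = 0.522 with an estimated correlation). Nuclear respiratory chain genes were lower in 13 of 24 (median −0.29), and in 6 without male SD replicate 4. In all 3108 of 16786 genes passed, 1838 higher and 1270 lower. The sex-biased lists (camera adjusted p = 6.53e-72 and 9.45e-94) passed with an estimated correlation (adjusted p = 2.42e-08 and 1.76e-09), and the Kupffer, monocyte and neutrophil lists (1.2e-07, 1.29e-08 and 6.83e-05) did not (adjusted p = 0.264, 0.171 and 0.264 with an estimated correlation).

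The response to each diet was then compared between the sexes. Of the 1499 genes higher on WD in females that were tested in both sexes, 1298 were also higher in males, against 330 expected, and 10 of 2316 female calls were opposite. For mCDHFD 1657 of 1975 and for mMASHD 1239 of 1530 were shared. In the test of the difference itself, 1087 genes passed for WD, 337 with a more positive response in females and 750 with a less positive one, 438 for mCDHFD (158 and 280) and 107 for mMASHD (51 and 56). Without male WD replicate 2 the WD count was 689. The mCDHFD count was 184, 211, 239, 242 and 287 without male mCDHFD replicate 3, female mCDHFD replicate 4, male SD replicate 4, male mCDHFD replicate 4 and female mCDHFD replicate 1. The mMASHD count ran from 56 without male mMASHD replicate 2 or female mMASHD replicate 1 to 304 without female SD replicate 4 (457 without the 3 libraries), with 59, 61, 66, 68 and 174 without male mMASHD replicate 3, male SD replicate 4, male mMASHD replicate 4, female mMASHD replicate 4 and male mMASHD replicate 1.

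Sex-biased genes were among these differences. Mup7, which fell in males and was near its SD level in females, differed by 4.83 ± 0.74 for WD (adjusted p = 0.000653) and by 3.54 ± 0.69 for mCDHFD. Selenbp2 differed by 4.27 ± 0.59 for WD and 3.66 ± 0.58 for mMASHD, and Cyp7b1 by 2.74 ± 0.35 for WD. Cyp2b9 rose in males on mCDHFD and stayed at 399.1 ± 33.8 CPM in females, a difference of −3.94 ± 0.51 (adjusted p = 8.19e-05). Male-biased genes had a more positive response in females in 12 of 20 for WD (13 adjusted over the list alone, median 1.83), 7 for mCDHFD (13 adjusted over the list alone) and 3 for mMASHD (7 adjusted over the list alone). All 20 were already lower in females on SD, so any near the floor there could not fall as in males. A difference of this list can therefore come from the fall in males alone. Neutrophil markers had a less positive response in females in 5, 6 and 2 of 11 (9, 9 and 7 adjusted over the list alone), with Cxcr2 at −3.43 ± 0.76 for WD, −4.26 ± 0.76 for mCDHFD and −3.91 ± 0.76 for mMASHD, and S100a8 at −3.03 ± 0.65 for WD and −3.35 ± 0.65 for mCDHFD. The monocyte list was less positive in 10 of 22 genes for WD (15 adjusted over the list alone) and 4 for mCDHFD (12 adjusted over the list alone). Neutrophil and monocyte genes, Cxcr2 and Ccl2 among them, were already higher in females than in males on SD. A less positive response therefore does not by itself mean a lower level in females on the diet. Cyp4a14 (2.71 ± 0.45), Cyp4a10 (2.18 ± 0.35) and Ehhadh (1.99 ± 0.34) fell less in females on mCDHFD. Ccnd1, a cyclin of cell cycle entry, differed by −2.43 ± 0.51 for WD and −2.67 ± 0.51 for mMASHD. By camera the male-biased list passed for WD and mCDHFD (3.48e-22 and 9.04e-16), also with an estimated correlation (adjusted p = 0.000801 and 0.00756), and for mMASHD (5.5e-08), but not there with an estimated correlation (adjusted p = 0.196). The neutrophil list passed for WD, mCDHFD and mMASHD (5.53e-08, 1.15e-13 and 1.48e-07), with adjusted p = 0.115, 0.0172 and 0.203 with an estimated correlation, and the monocyte list for WD and mCDHFD (1.69e-11 and 1.99e-11), with adjusted p = 0.115 and 0.0898. For mMASHD the monocyte list had 0.0396, and adjusted p = 0.596 with an estimated correlation. That call ended without male SD replicate 4 (0.325), male mMASHD replicate 3 (0.202) or 4 (0.0927), female SD replicate 3 (0.38) or female mMASHD replicate 1 (0.202) or 4 (0.0934).

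The difference between mMASHD and WD was also tested between the sexes, a comparison added after the data were seen. It passed for 102 genes, 57 more positive and 45 less positive in females. None of the alternatives, the clock score or the leaving out of libraries was run for this comparison. The libraries with transcripts of other tissues stayed in it, and how far its calls depend on single libraries is not known. Cyp51, higher on mMASHD than on WD in males, differed by −1.78 ± 0.29 (adjusted p = 0.00769), and Gpnmb, lower on mMASHD in males, by 2.29 ± 0.53 (adjusted p = 0.0419). Mmp12 differed by 1.76 ± 0.36 and Lgals3 by 1.28 ± 0.25.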

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

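The tests on the 3 libraries with transcripts of other tissues and on the clock genes were chosen after the result was seen.

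Across 320 combinations of a group and a measure, 14 had a library far from the other 3 of its group, where chance gives about 16, and they fell on 11 libraries. The gap to the nearest library, as a share of the group's range, was 0.882 for the clock score and 0.879 for the lipid droplet list (female mMASHD replicate 4, highest and lowest), 0.954 for the bile acid list (male WD replicate 3, highest), and 0.854 for collagen and 0.940 for macrophage markers (male mMASHD replicate 1, lowest in both). It was 0.877 for stellate cell markers and 0.961 for interferon genes (male SD replicate 2, highest in both), 0.8497 for the monocyte list (female mCDHFD replicate 3, highest) and 0.872 for T and NK cell markers (male mMASHD replicate 3, highest). It was 0.948 for ER stress genes (male mMASHD replicate 4, highest), 0.949 for glucose metabolism (male SD replicate 4, highest), 0.832 for male-biased genes (male mMASHD replicate 2, lowest), 0.928 for X-inactivation and Y-linked genes (female mMASHD replicate 2, lowest) and 0.840 for immediate early genes (female WD replicate 3, highest).

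The response to WD differed between the sexes for 1087 genes. In female minus male log2 fold changes these included Mup7 (4.83), Selenbp2 (4.27), Serpina1e (4.00), Elovl3 (3.16), Rgs16 (−3.30), Cyp2b9 (−3.25), Ephb2 (−3.21), Themis (−2.82), Tlr1 (−2.72), Ccl2 (−1.98), Cidec (−1.77), Mki67 (−1.69) and Cd36 (−0.96). Acta1 (4.34) is a muscle gene, at 37.1 ± 69.4 CPM in female WD through replicate 4. Of the lists 25 differed, 1 also with an estimated correlation. The response to mCDHFD differed for 438 genes, among them Mup7 (3.54), Cyp2c40 (2.77), Cyp4a14 (2.71), Acot3 (2.52), Selenbp2 (2.385), Cyp2b9 (−3.94), Rgs16 (−2.88), Lcn2 (−2.85), Sell (−2.75), Serpina7 (−2.66) and Ccl2 (−2.17), and for 21 lists, 2 of them also with an estimated correlation. The response to mMASHD differed for 107 genes, among them Selenbp2 (3.66), Gstp2 (2.45), Cyp2c40 (2.38), Adam11 (2.28), Cyp2c70 (2.20), Rgs16 (−3.72), Sult2a7 (−3.68), Themis (−3.40), Ccnd1 (−2.67) and Aacs (−2.25), and for 21 lists, 0 of them by camera with an estimated correlation. With the clock score as a covariate 16 of the 69 calls of named genes ended for WD, 0 of 47 for mCDHFD and 3 of 24 for mMASHD. Some of the calls listed here also ended when 1 of the 16 libraries was left out. For WD that was so without 1 library for Themis (−1.73, adjusted p = 0.222, without female SD replicate 4) and Tlr1 (−1.99, adjusted p = 0.0513, without female SD replicate 3), and in 7, 10, 11, 11 and 12 of 16 cases for Acta1, Ccl2, Cidec, Cd36 and Mki67, with sizes down to 0.42, −1.70, −0.91, −0.78 and −1.24. For mCDHFD it was so in 1 case for Selenbp2 (1.98, adjusted p = 0.0596, without male SD replicate 2) and in 7, 12 and 13 cases for Sell, Ccl2 and Rgs16, with sizes down to −2.14, −1.93 and −2.27. For mMASHD it was so in 3 cases for Themis (−2.31, adjusted p = 0.136, without female SD replicate 4), 4 each for Gstp2 and Cyp2c40 (1.81 and 1.62 without male SD replicate 3) and 5 for Rgs16 (−3.11 without female SD replicate 1). Leaving out male SD replicate 4 moved Rgs16 the other way, to −4.05 for mCDHFD and −4.88 for mMASHD. Without the 3 female libraries with transcripts of other tissues Themis was at −1.73 for WD (adjusted p = 0.252) and −2.49 for mMASHD (adjusted p = 0.117), Mki67 at −1.22 (adjusted p = 0.16), Acta1 at 0.48 (adjusted p = 0.609) and Sell at −2.14 (adjusted p = 0.0811). Of the genes that kept their call, Rgs16 for WD was at −2.69 without female SD replicate 1 and without male WD replicate 1, −4.07 without female WD replicate 4, −4.34 without the 3 libraries and −4.47 without male SD replicate 4, Cyp2b9 for WD was at −2.54 without male WD replicate 2, and Cyp2c40 for mCDHFD at 2.01 without male SD replicate 3.

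Genes of other tissues stood out in 3 female libraries. Of the list genes under 5 CPM in the other female libraries, 83.3% of the lymphoid genes (5 of 6) were highest in female SD replicate 4, 100% of the muscle genes (15 of 15) in female WD replicate 4 and 100% of the adrenal genes (5 of 5) in female mMASHD replicate 3, so pieces of those tissues may have been sampled with the liver. Over whole lists the numbers were 8 of 12, 16 of 16 and 5 of 11, and 6, 1 and 6 of those genes are also expressed at 5 CPM or more in the other female libraries. Among genes with a mean under 5 CPM over all 16 female libraries, which treats the libraries alike, they were 5 of 6, 13 of 13 and 5 of 5, and no other library was highest for more than 1, 0 and 0 of them. All 6 fat genes were highest in female WD replicate 4 (median 46.6 times their median elsewhere), and in female SD replicate 4, highest for 0 of the 6, that ratio was 16.7. These are low levels, with medians of 4.29 and 1.13 CPM in the 2 libraries against 0.0742 CPM elsewhere. The adrenal list as a whole stood at a median of 1.35 times its level elsewhere, so adrenal tissue rests on 5 genes of low level. The lymphoid list as a whole stood at 1.85 times. Its genes under 5 CPM elsewhere had a median of 4.14 CPM in female SD replicate 4 against 1.02 CPM elsewhere, so lymphoid tissue also rests on few genes of low level. The most abundant listed genes were Cd74 (209 CPM in that library, up to 529 elsewhere), Myh2 (115 CPM, at most 1.09 elsewhere) and Dhcr24 (618 CPM, up to 736 elsewhere). Depth is argued against, since 0 of the 3 libraries had the highest total of its group, and no biological explanation was tested.

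Changes against SD were larger in males than in females. After removal of the part due to standard errors, the SD of log2 fold changes was 0.69 in males and 0.41 in females on WD, a ratio of 1.71, with ratios of 1.47 on mCDHFD and 1.33 on mMASHD over 9914 genes. These ratios share the same chow animals of each sex, so they are not independent. A shift in a whole chow group would enter each of them, and leaving out 1 library cannot exclude it. Bounds of 1.1 were set before these ratios were computed, and the lowest ratio was 1.26 without the 3 libraries, 1.23 without any 1 library and 1.28 with the clock score as a covariate, which argues against other tissues, a larger female spread and clock phase as the whole cause. A difference between the sexes in the response to diet may account for it, and stays open together with differences in food intake or weight, which were not analysed here.

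Clock genes moved between male SD and the male diets. All 13 clock genes past the threshold on WD moved as their set does over the day, and so did all 12 on mCDHFD and all 10 on mMASHD. The mean clock score of the male diets lay 5.25, 4.46 and 4.07 above male SD. The widest range within a male group, 4.82 on mMASHD, lies between these values, so it does not decide whether diet and sex alone set the score. In females on WD, mCDHFD and mMASHD the range within a group was 5.60, 6.81 and 4.95. Each exceeded the distance of that group's mean from female SD, 2.37, 4.15 and 1.92. A time of day at sampling that differed between groups may be the cause, but it cannot be told apart from an effect of diet on the clock, since the labels give no sampling times.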

How the results depend on the processing

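The settings without the 3 female libraries, with every library drawn down to the lowest total and with the clock score were chosen after the data were seen.

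The 6 comparisons of a diet with SD kept counts within 1.5 times under DESeq2, its size factors, both filters, the robust spread, the block, the animal number and the lower depth. With the clock score as a covariate males had 2291 (WD), 2897 (mCDHFD) and 1803 (mMASHD) genes and females on mCDHFD 1510. On WD in males the median size of the log2 fold changes went from 0.70 to 0.63 and their standard error from 0.15 to 0.27, and 98.6% of them kept their sign, so calls ended mostly through the wider error. With the 8 compared libraries alone females had 1468 (WD) and 1292 (mMASHD), where fewer samples estimate the spread.

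Comparisons between diets moved more. Between mCDHFD and WD in males the 1 gene became 64 with DESeq2, 2 with the animal number, and 0 at the lower depth, with the clock score and with the 8 libraries alone. In mCDHFD against mMASHD in males DESeq2 gave 1074. In females mCDHFD against WD gave 133 with DESeq2, 5 with the replicate block, 29 with the animal number, 8 without the 3 libraries and 88 with all 32 libraries in a single fit. In females mMASHD against WD gave 23 with DESeq2, 8 with the animal number and 27 with all 32 libraries. In females mCDHFD against mMASHD gave 77 with DESeq2, 4 without a filter, 3 with the animal number, 4 without the 3 libraries, 11 with the 8 libraries alone and 17 with all 32 libraries. The sex difference in the response to mCDHFD had 830 genes with DESeq2, and that to mMASHD 326 with DESeq2, 184 with the animal number and 457 without the 3 libraries. Apart from the lower depth and the fewer samples, the cause was not tested.

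Leaving out each library in turn gave 5782 to 6618, 5646 to 6473 and 4436 to 5629 genes in males on WD, mCDHFD and mMASHD against SD, and 1522 to 2716, 2120 to 3743 and 1379 to 2985 in females, each highest without female SD replicate 4. Between diets it gave 0 to 2, 516 to 1118 and 214 to 603 in males (mCDHFD against WD, mMASHD against WD, mCDHFD against mMASHD) and 0 to 21, 0 to 2 and 0 to 3 in females (mCDHFD against WD, mMASHD against WD, mCDHFD against mMASHD). The differences in response ran over 689 to 1205 (WD), 184 to 563 (mCDHFD) and 56 to 304 (mMASHD), and the sexes on SD over 2260 to 2987.

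A value counts as reversed when a called gene changed sign or a called list changed direction in camera, and 11 of the reversed values belong to the clock score, which is made from Dbp and removes what moves with it. With it Dbp, Per3 and Bhlhe41 changed by −0.004674, −0.07415 and −0.4311 on WD, −0.08132, −0.3148 and −0.5024 on mCDHFD and −0.08585, −0.3511 and −0.3241 on mMASHD in males, and Dbp and Per3 by −0.363 and −0.06057 on mCDHFD in females. The median of the collagen list in females, mMASHD against WD, was 0.08603, ran from −0.03836 without female mMASHD replicate 3 to 0.1939 without replicate 1, and was −0.02229 without female WD replicate 3 and −0.02321 without the 3 libraries. For B and plasma cell markers the sex difference in the response to mCDHFD was 0.08971 without the 3 libraries, and ran from −1.715 without female SD replicate 1 to 0.09015 without female SD replicate 4. Saa2 between the sexes on SD was −2.91, with −3.384 without female SD replicate 4 and 0.7045 without male SD replicate 2. The sexes overlapped in Saa2, with that library at 1258 CPM, the other SD males at 22.5 to 36.02 CPM and the SD females at 24.95 to 81.26 CPM. The medians of other called lists in females also changed sign as their calls ended. Red blood cell genes, mCDHFD against mMASHD, went from 0.8792 to −0.09657 without female mCDHFD replicate 2, and glucose metabolism, mCDHFD against SD, from −0.1 to 0.001766 without female SD replicate 1. Fatty acid synthesis, WD against SD, went from 0.1144 to −0.1095 without the 3 libraries and −0.03931 without female SD replicate 4. For mMASHD against WD, B and plasma cell markers went from −0.5376 to 0.1587 and sinusoidal endothelial markers from −0.1621 to 0.009764 without the 3 libraries.

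Of 1138 calls of named genes 271 ended or reversed with the clock score, 57 with the animal number, 53 without a filter, 52 with the block, 44 with the robust spread and 3 with size factors. Others were 90 of 585 without the 3 libraries, 78 of 856 with the 8 libraries alone, 63 of 879 with all 32 libraries, 24 of 1136 at the lower depth and 3 of 1115 with the 1 CPM filter. With DESeq2 0 of 1137 ended and 14 genes gained a call. Leaving out a library ended 1404 of 10224 and reversed 1. Of 286 list calls, 266 (93%) were lost with an estimated correlation.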

Other observations

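The sex difference between mMASHD and WD was added after the data were seen.

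Ldlr, the gene targeted in these mice, had fewer reads on WD and mCDHFD in males. In males it stood at 543 ± 81.6 CPM on SD, 348.8 ± 49.4 on WD, 350.7 ± 38.1 on mCDHFD and 480.5 ± 116.5 on mMASHD. In females it stood at 476.7 ± 103.4, 434.9 ± 48.4, 383.6 ± 9.003 and 405.4 ± 57.4 CPM. In males it changed by −0.64 ± 0.16 on WD (adjusted p = 0.00349) and −0.63 ± 0.16 on mCDHFD (adjusted p = 0.00383). With the clock score as a covariate the values were −0.73 ± 0.2999 (adjusted p = 0.122) and −0.71 ± 0.27 (adjusted p = 0.0805), so these calls ended through a wider error and not a smaller change. It did not pass on mMASHD in males (adjusted p = 0.406) or on WD, mCDHFD and mMASHD in females (adjusted p = 0.591, 0.139 and 0.309), but passed on mCDHFD in females without the 3 libraries with transcripts of other tissues (−0.45, adjusted p = 0.00543). The fetal RNA H19 spread widely in females, at 0.4499 CPM on SD and 15.2 ± 20.4, 5.27 ± 7.02 and 22.1 ± 20.4 CPM on WD, mCDHFD and mMASHD.

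The authors' deposited tables call 7000, 6789 and 5825 genes in males on WD, mCDHFD and mMASHD against SD, and 2794, 3658 and 2787 in females. Of the genes called here, 97.4, 97.4 and 97.7% in males and 99.1, 99.4 and 99.4% in females are also called there, all in the same direction. In the deposited KEGG results, of 338 pathways 93, 111 and 95 pass in males and 84, 60 and 50 in females. Staphylococcus aureus infection has the highest score in males (2.13, 2.28 and 2.07), and Retinol metabolism falls (−1.81, −1.93 and −1.89). In females Cytoskeleton in muscle cells leads on WD (2.44) and Cortisol synthesis and secretion on mMASHD (2.09). Without female WD replicate 4 the muscle list on WD went from 4 to 1 of 9 genes higher (median 1.96 to −0.27). Without female mMASHD replicate 3 the adrenal list on mMASHD kept 1 of 6 (median 0.18 and 0.21). Only 6 of the 11 adrenal genes were tested there, and the 5 that mark that library had a median of 0 CPM elsewhere. These values therefore do not decide whether adrenal tissue raised the Cortisol synthesis score.

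Cholesterol synthesis genes were higher on mMASHD than on WD in males, and clock phase was weighed as a source. With the clock score as a covariate 16 genes of the list were higher, against 15 without it, with a median of 0.77 against 0.69. The bound set before this count, for clock phase as the cause, was fewer than 5 genes, so these values argue against it. The diets differ in fat source, which may matter, but no test here separates that from their other differences.

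The 8 libraries of each comparison were also split into other groups of 4, in all 35 ways. The lowest share such a test can give is 1 of 35, without a correction over the comparisons. Where the groups differ, the other splits mix animals of both, which widens the fitted spread and lowers their counts. A real split that stands alone therefore makes chance less likely but does not exclude it. The real split alone gave as many genes, 1 of 35 splits, for WD, mCDHFD and mMASHD against SD in males (6781, 6628 and 5658 genes, with at most 1, 0 and 33 in the others) and in females (2345, 3230 and 2311, with at most 0, 69 and 343). It was also so for mMASHD against WD (1199, at most 4) and mCDHFD against mMASHD (529, at most 4) in males, mCDHFD against WD in females (16, at most 2) and the sexes on SD (3108, at most 885). The real split did not stand apart for mCDHFD against WD in males, where 4 of 35 splits gave at least the 1 gene and up to 2. Nor did it in females for mMASHD against WD and mCDHFD against mMASHD, where it gave 0 genes by edgeR, as many as or fewer than all 35. For the differences in response between the sexes 100 draws of sex labels were made. As many genes came from 1 draw for WD (1087, highest other 928), 3 for mCDHFD (438, highest other 1166), 4 for mMASHD (107, highest other 1045) and 3 for mMASHD against WD (102, highest other 725), the real split included. The other draws with at least as many genes as the real one kept or exchanged the sex of all 8 animals of a compared diet, so they hold the sex difference between the livers. Draws that did neither gave at most 2 (WD), 4 (mCDHFD), 41 (mMASHD) and 3 (mMASHD against WD) genes. Those draws put both sexes in a group, so the sex difference widens the fitted spread and lowers their counts. The draws therefore do not decide whether chance could give the differences in response.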
